A study of Saccharomyces cerevisiae with 84 samples.

How the data were processed

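Saccharomyces cerevisiae BY4743, a diploid strain, was grown in rich medium and exposed for 2 h to silver, arsenite, cadmium, chromium, copper, mercury or zinc at the doses that the labels give as EC10 and EC50. Each of 84 arrays set treated against untreated RNA, with 6 arrays in each of 14 groups of metal and dose. The series text gives 3 isolates and a technical dye swap, but the labels do not say which arrays share an isolate. Whether untreated RNA was a shared pool is not stated. The growth of each culture after treatment is not given in the sources used here.

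The scanner files hold, per the file headers, the mean pixel intensity of each spot and the median intensity of its local background in red (Cy5) and green (Cy3). The deposited files also hold processed intensities, which Agilent Feature Extraction A.7.5.1 had detrended and normalized between dyes with rank-consistent lowess, and the log10 ratio of red over green. The series matrix deposited by the authors holds the natural log of treated over untreated cells for 6256 open reading frames, with 6361 missing values and a floor at a ratio of 0.01. This was read from the values, which correlated with the scanner ratios at r = 0.951 to 0.997 (median 0.990) with slopes of 0.943 to 0.998. Every array had 10807 spots, 10263 for genes and 544 controls, and each open reading frame had 1 probe, spotted 2 times for 4007 probes and 1 time for 2249. Of the 6256 identifiers, 5756 were in the reference gene table, which gave their symbols, and 500 were not and keep their identifier.

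Spots marked by the scanner as uneven or deviating were left out, 0 to 192 per array. Saturated spots, 9 to 142 per array, were kept, and a ratio with a channel saturated on all 6 arrays is given as a bound. Signals were corrected for background with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with no step between arrays. Ratios were turned to treated over untreated cells, and spots of a probe were averaged. Probes well above background in either channel on at least 3 arrays of 1 group were kept (6245), and 6230 with at least 2 of the 3 pair values in every group were tested. In these, 540 pair means were missing, in 467 genes.

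The unit of replication was the dye-swap pair, the mean of 2 arrays of opposite dyes, so that a constant dye effect cancels. In each group the 3 pairs were those of the 6 possible matchings with the highest mean correlation of the arrays' deviations from their orientation's mean. That correlation was 0.119 to 0.499 (median 0.264), against a median of 0.107 for the next best matching, lowest in arsenite at EC50 (0.119 against 0.101, with 1 chosen pair at -0.0609), and 10 of the 42 pairs lay on 1 slide. The titles' replicate numbers do not pair arrays across doses: of 42 correlations between equal numbers 17 were over 0.1, they ran from -0.406 to 0.36, and the own number was the best match in 10.

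A linear model in limma with empirical Bayes (residual df 28, prior df 6.53, median residual SD 0.0749) gave each of the 14 groups a mean, tested against 0. Ratios tested against 0 leave out the control's own spread if the untreated RNA was a shared pool, which is not known. Contrasts set EC50 against EC10 of a metal, and a metal against the mean of the other 6 at EC50 and at EC10. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison and at least 2-fold change. Genes called in all 7 metals were counted beside the number that independent lists would share. Profiles were compared by Pearson and Spearman correlation across genes, without a p, beside 20 simulations of a shared control. The procedure was tested on simulated data of 6245 genes: 100% of 100 genes changed by 1.5 and of 100 changed by 3 (log2) were recovered in each kind of comparison, with 0 calls among unchanged genes, and 100% of 42 simulated pairs were matched when isolates gave 0.3 of the variance. Genes were simulated as independent of each other, so the matching there does not show that the pairs chosen in the data share an isolate.

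Gene lists of 4 or more measured members, 30 in all, were tested in each group with camera (correlation between genes 0.01), adjusted over 420 tests, and with a correlation estimated from the data (median 0.14, highest 0.571) as an alternative. The report gives the results of the lists for sulfur and methionine, iron uptake, zinc, copper detoxification, copper uptake, arsenic transport, oxidative defence, aryl-alcohol dehydrogenases, heat shock, general stress, proteasome, ribosome biogenesis, cytosolic and mitochondrial ribosomal proteins, respiration, glycolysis, hexose transporters, ergosterol, hypoxia and heme, phosphate, drug efflux, DNA damage, amino acid synthesis, unfolded protein, cell wall, histones, cell cycle, haploid mating, meiosis and seripauperins. The pattern that defined the cytosolic ribosomal proteins also took RPP1, a subunit of RNase P. Members of the copper detoxification, hexose transporter, acid phosphatase, aryl-alcohol and seripauperin families are near-identical, so their probes may share signal.

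Genes were named by a rule: for each metal at EC50 the 6 largest rises and 6 largest falls among called genes with 1 sign in all 3 pairs, at EC10 the 3 largest each way, between doses the 3 largest each way, against the other metals the 5 higher and 3 lower, up to 8 each way called in all 7 metals, up to 4 called members of a called list, and 23 metal response genes always reported. Some were left out for length, and genes outside the rule are marked where they appear. The design, comparisons, lists, naming rule and alternatives were set before the data were examined, except the slide or the chosen pair as a random block, the metal pairs set against each other and the tests that the closing section names as chosen later. The alternatives were processed signals, median centring, no background correction, no filter or a stricter filter on dim probes (80% of arrays in each channel, 6058 genes), consecutive pairs, separate arrays with a dye term, groups fitted alone, array weights, series matrix values, no minimum fold, a replicate number block and leaving out each pair. The number of arrays limits the precision.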

Results

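Transcript levels were measured in BY4743, a diploid laboratory strain of the budding yeast Saccharomyces cerevisiae, after 2 h in rich medium with 1 of 7 metal salts. Each metal was given at 2 doses, which the labels give as EC10 and EC50 without naming the effect measured. These were silver nitrate at 10 and 20 µM, sodium arsenite at 0.4 and 1.25 mM and cadmium chloride at 5 and 25 µM. The others were chromium trioxide at 0.4 and 1.7 mM, copper sulfate at 5 and 9 mM, mercuric chloride at 18.8 and 46.8 µM, and zinc sulfate at 1 and 2 mM. Every array set treated RNA against untreated RNA in the other dye. The 14 groups of metal and dose held 6 arrays each, 84 in all, and the 6 arrays of a group were read as 3 dye-swap pairs. The 84 arrays carried probes for 6256 open reading frames, of which 6230 were tested. Between 93.5% and 99.2% of the gene probes were well above background in each channel of an array, with median intensities of 565 to 1550 in green and 498 to 2046 in red over local backgrounds of 270 to 301. The mean log2 ratios of the opposite dye orientations correlated across genes at r = 0.782 to 0.953 within a group. Values below are log2 ratios of treated over untreated cells, as mean ± SD of n = 3 pairs. A gene was called when its limma adjusted p was under 0.05 and its change at least 2-fold. These ratios were tested against 0. Such tests leave out the untreated cells' own spread if the untreated RNA was a shared pool, and the labels do not state whether it was.

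**Figure D1:**
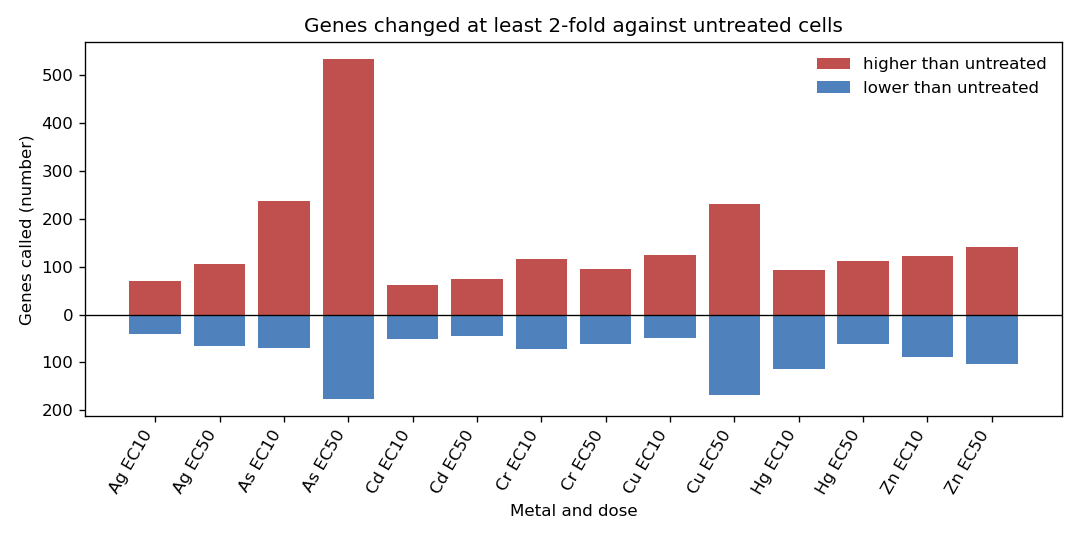
Number of genes called higher (positive bars) and lower (negative bars) than in untreated cells for each metal at EC10 and EC50. Arsenite at EC50 gave 533 higher and 177 lower genes, and copper at EC50 gave 231 higher and 168 lower.

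Against untreated cells, silver raised the copper metallothionein CUP1 and the high-affinity iron uptake pair and lowered a copper transporter. At EC50 CUP1-1 (YHR053C) reached 3.64 ± 0.070 and its near-identical copy CUP1-2 (YHR055C), which the probes cannot tell apart from it, 3.68 ± 0.14. FET3 (YMR058W), the multicopper oxidase of high-affinity iron uptake, rose by 1.79 ± 0.061 and its permease partner FTR1 (YER145C) by 1.23 ± 0.060, whereas the copper transporter CTR1 (YPR124W) fell (-1.65 ± 0.14). The heat shock gene HSP30 (YCR021C), a plasma membrane protein, rose by 2.22 ± 0.12, the peptide transporter PTR2 (YKR093W) by 1.98 ± 0.061 and the polyamine exporter TPO2 (YGR138C) by 1.82 ± 0.075. The glucose transporters HXT6 (YDR343C) and HXT7 (YDR342C), a further near-identical pair, fell (-2.10 ± 0.017 and -2.08 ± 0.20), as did RGI1 (YER067W), a gene of respiratory growth (-2.25 ± 0.038), and the hexokinase HXK1 (YFR053C, -1.85 ± 0.13). Of 66 ribosome biogenesis genes, 12 rose and none fell at EC50, among them the GTPase NOG2 (YNR053C, 2.04 ± 0.018) and the RNA helicase DBP8 (YHR169W, 1.78 ± 0.086). Of 137 cytosolic ribosomal protein genes 6 rose, including RPS8A (YBL072C, 1.68 ± 0.058), while of 46 respiration genes 2 fell, the succinate dehydrogenase subunits SDH2 (YLL041C, -1.15 ± 0.10) and SDH1 (YKL148C, -1.07 ± 0.093).

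As whole lists at silver EC50, ribosome biogenesis, cytosolic ribosomal proteins and copper detoxification were higher. For copper detoxification 2 of 4 members were called, the near-identical CUP1 pair, so that list result may rest on 1 signal. Respiration, proteasome subunits (1 of 36 called, RPN9 (YDR427W), at -1.14 ± 0.073) and general stress genes (6 of 34 lower, 1 higher) were lower (for the 6, camera adjusted p between 7.63e-14 and 0.00125, and adjusted p between 0.0677 and 0.488 with an estimated correlation). Sulfur and methionine genes, with no called member, and cell cycle genes with 1 were also higher as lists, and mitochondrial ribosomal proteins, histones, phosphate and cell wall genes lower (camera adjusted p between 0.0136 and 0.0439, and adjusted p between 0.42 and 0.718 with an estimated correlation). In limma, silver changed 71 genes higher and 41 lower at EC10 and 105 higher and 65 lower at EC50. With median centring in place of loess the split was 57 to 57 and 94 to 123, and with the scanner's processed signals 173 to 167 at EC50. The totals at EC50 ran from 62 without background correction to 340 with processed signals, and the calls of SDH1, SDH2 and RPN9 were lost in the former (log2 -0.95, -0.94 and -0.98).

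Arsenite gave the largest number of calls of the 7 metals at each dose. At EC50 the old yellow enzyme OYE3 (YPL171C), an NADPH dehydrogenase, rose by 7.72 ± 0.068, the oxidative stress gene OSI1 (YKL071W) by 7.10 ± 0.16, and the small heat shock protein HSP26 (YBR072W) by 7.08 ± 0.25. The multidrug exporter FLR1 (YBR008C) rose by 6.70 ± 0.040 and the glutathione transferase GTT2 (YLL060C) by 6.41 ± 0.014. The arsenite exporter ARR3 (YPR201W) rose by 4.17 ± 0.23 at EC10 and 3.93 ± 0.089 at EC50, and YCF1 (YDR135C), which carries glutathione conjugates into the vacuole, by 1.97 ± 0.047 and 2.48 ± 0.099. Of 27 sulfate assimilation and methionine genes, 23 rose at either dose. They included the sulfate permease SUL1 (YBR294W, 6.24 ± 0.34 at EC50) and the first enzymes of sulfate reduction, MET3 (YJR010W, 5.46 ± 0.072), MET14 (YKL001C, 4.25 ± 0.024) and MET16 (YPR167C, 3.32 ± 0.30). GSH1 (YJL101C), the first enzyme of glutathione synthesis, rose by 2.94 ± 0.079. Among the genes that fell furthest at EC50 were CTR1 (-3.30 ± 0.076), the fatty acid desaturase OLE1 (YGL055W, -2.82 ± 0.064), the zinc transporter ZRT1 (YGL255W, -2.81 ± 0.059) and the cell wall protein PIR1 (YKL164C, -2.46 ± 0.037).

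Of 27 thioredoxin, glutathione and peroxide defence genes, 17 rose at arsenite EC50, with thioredoxin TRX2 (YGR209C) at 3.36 ± 0.063. Heat shock genes rose in 22 of 27, with the inducible Hsp70 SSA4 (YER103W) at 3.44 ± 0.12. Drug efflux genes rose in 9 of 14, with the ABC exporter SNQ2 (YDR011W) at 3.59 ± 0.14, as did 4 of 6 aryl-alcohol dehydrogenases, with AAD6 (YFL056C) at 6.02 ± 0.056. Among DNA damage genes 9 of 19 rose, including the ribonucleotide reductase genes RNR4 (YGR180C, 3.03 ± 0.092) and RNR3 (YIL066C, 1.87 ± 0.17) and the repair gene RAD54 (YGL163C, 1.88 ± 0.030). That list was higher in camera with adjusted p = 3.55e-05, and adjusted p = 0.0141 with an estimated correlation. The sulfur, oxidative, heat shock, drug efflux and aryl-alcohol lists were higher (camera adjusted p between 1.39e-11 and 0.000505, and adjusted p between 0.0572 and 0.187 with an estimated correlation). Copper detoxification (3 of 4, the CUP1 pair among them), iron uptake (12 of 27 higher, 1 lower) and general stress genes (13 of 34 higher, 3 lower) were higher as lists. So were the proteasome (1 of 36, its transcription factor RPN4 (YDL020C), at 2.85 ± 0.045) and the PAU seripauperins (0 of 24), a family whose probes can cross-hybridise (for these 5, camera adjusted p between 2.13e-07 and 0.00493, and adjusted p between 0.0677 and 0.648 with an estimated correlation). The proteasome median was 0.55, against 0.080 with median centring and 0.31 in the series matrix.

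Histones fell in 5 of 10 at arsenite EC50, with histone H4 gene HHF2 (YNL030W) at -1.83 ± 0.15, and cytosolic ribosomal proteins in 13 of 137 with 1 higher, among them RPS28A (YOR167C) at -1.46 ± 0.23. Ergosterol genes fell in 4 of 23, with ERG6 (YML008C) at -1.48 ± 0.069, and zinc genes in 5 of 19. Copper uptake genes fell in 4 of 6, phosphate genes in 3 of 17, and ribosome biogenesis and mitochondrial ribosomal proteins in 1 member each. As lists these 8 were lower (camera adjusted p between 5.02e-11 and 0.0479, and adjusted p between 0.0734 and 0.734 with an estimated correlation). Respiration was higher as a list (median 0.21, adjusted p = 0.0239, and adjusted p = 0.718 with an estimated correlation), but its median was -0.11 with median centring. In limma, arsenite changed 238 genes higher and 70 lower at EC10 and 533 higher and 177 lower at EC50. The split was 298 to 165 and 639 to 388 with processed signals, 495 to 399 at EC50 with median centring, and 274 to 162 and 548 to 451 in the series matrix, where the median of all genes shifted by -0.125 at EC50.

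With cadmium, SUL1, MET3 and MET14 of sulfate assimilation rose and the zinc transporter ZRT1 fell. At EC50 SUL1 rose by 3.00 ± 0.062, MET3 by 2.91 ± 0.13, MET14 by 2.72 ± 0.15 and the sulfite reductase subunit MET5 (YJR137C) by 2.53 ± 0.094. HSP30 rose by 2.86 ± 0.22, TPO2 by 2.73 ± 0.018 and the Pho85 cyclin PCL1 (YNL289W) by 2.24 ± 0.28. ZRT1 fell at both doses (-1.66 ± 0.22 at EC10 and -2.95 ± 0.10 at EC50), as did RGI1 (-2.19 ± 0.19 at EC50), TMA10 (YLR327C), a ribosome-associated protein (-2.42 ± 0.089), HXT6 (-2.17 ± 0.19) and the glycine decarboxylase subunit GCV1 (YDR019C, -1.73 ± 0.24). CUP1-1 was lower in cadmium at EC50 (-1.02 ± 0.061), a call lost when 1 pair was left out (-0.99) and without background correction (-0.90).

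Of the 27 sulfur genes 10 rose at cadmium EC50 and 4 at EC10, where the methionine permease MUP1 (YGR055W) reached 1.40 ± 0.21. Ribosome biogenesis (5 of 66, NOG2 at 1.69 ± 0.084), cytosolic ribosomal proteins (3 of 137, RPS8A at 1.70 ± 0.036), and iron uptake (1 of 27) were higher as lists at EC50. Cell cycle genes (1 of 20), seripauperins (0 of 24) and the sulfur genes were too (for these 6, camera adjusted p between 6.11e-12 and 0.0276, and adjusted p between 0.459 and 0.734 with an estimated correlation). General stress genes (3 of 34 lower, including the glycogen phosphorylase GPH1 (YPR160W) at -1.57 ± 0.13, and 2 higher), copper uptake (2 of 6) and amino acid synthesis (1 of 39) were lower as lists. So were the proteasome, respiration and mitochondrial ribosomal protein lists, with no called member (for these 6, camera adjusted p between 3.08e-05 and 0.0472, and adjusted p between 0.136 and 0.648 with an estimated correlation). In limma, cadmium changed 62 genes higher and 51 lower at EC10 (53 to 89 with median centring) and 75 higher and 45 lower at EC50. The totals ran from 49 without background correction to 200 with processed signals at EC10, and from 69 to 207 at EC50.

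With chromium, GSC2, FRE7, FRE1 and ARN2 rose. At EC50 GSC2 (YGR032W), the stress-induced subunit of 1,3-beta-glucan synthase, rose by 3.88 ± 0.062, the membrane protein YRO2 (YBR054W) by 2.75 ± 0.052, PCL1 by 2.71 ± 0.20 and the secreted glycoprotein YGP1 (YNL160W) by 2.41 ± 0.060. The metalloreductases FRE7 (YOL152W) and FRE1 (YLR214W), which serve copper and iron uptake, rose by 2.28 ± 0.18 and 1.68 ± 0.059, and the siderophore transporter ARN2 (YHL047C) by 1.88 ± 0.17. The cell wall mannoprotein CWP1 (YKL096W) fell (-2.56 ± 0.12), as did the acid phosphatases PHO11 (YAR071W) and PHO12 (YHR215W), a near-identical pair (-1.76 ± 0.098 and -1.83 ± 0.10), and the arginine gene ARG1 (YOL058W, -1.72 ± 0.11). HSP12 (YFL014W), a membrane stress protein, fell at EC10 (-2.13 ± 0.11), and at EC50 it was at -1.41 ± 0.19, a call lost without background correction (-0.98).

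At chromium EC50 copper uptake (2 of 6), iron uptake (5 of 27) and sulfur genes (10 of 27, with MET2 (YNL277W) at 1.71 ± 0.15) were higher as lists. Drug efflux (4 of 14), cell cycle genes (1 of 20) and seripauperins (0 of 24) were higher too (for these 6, camera adjusted p between 7.09e-08 and 0.0107, and adjusted p between 0.0628 and 0.502 with an estimated correlation). Histones (2 of 10, with the H2B gene HTB1 (YDR224C) at -1.18 ± 0.11), amino acid synthesis (3 of 39, with the leucine gene LEU1 (YGL009C) at -1.37 ± 0.075) and the proteasome (1 of 36) were lower. The same held for respiration and mitochondrial ribosomal proteins, with no called member (for these 5, camera adjusted p between 1.27e-05 and 0.0347, and adjusted p between 0.128 and 0.734 with an estimated correlation). In limma, chromium changed 115 genes higher and 71 lower at EC10 (103 to 108 with median centring) and 96 higher and 62 lower at EC50 (90 to 102). The totals ran from 83 without background correction to 307 with processed signals at EC10, and from 87 to 273 at EC50.

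With copper, the metallothionein CUP1-1 rose and CTR1 fell. CUP1-1 rose by 5.05 ± 0.042 at EC10 and 5.60 ± 0.15 at EC50, where its treated channel was saturated on all 6 arrays, so that the ratio is a bound of at least 48.5-fold. SOD1 (YJR104C), the copper-zinc superoxide dismutase, rose by 1.94 ± 0.095. CTR1 fell at both doses (-4.29 ± 0.15 and -4.06 ± 0.18), as did FRE1 (-2.67 ± 0.097 and -2.48 ± 0.063) and the sodium-phosphate transporter PHO89 (YBR296C, -2.84 ± 0.13 and -2.78 ± 0.060). At EC50 HSP26 rose by 5.37 ± 0.043, PTR2 by 3.89 ± 0.15, SSA4 by 3.66 ± 0.11, YGP1 by 3.51 ± 0.11, the aldehyde dehydrogenase ALD3 (YMR169C) by 3.23 ± 0.11 and HSP12 by 3.09 ± 0.22. ZRT1 fell (-2.73 ± 0.093), as did ARO10 (YDR380W), a decarboxylase of aromatic amino acid breakdown (-2.49 ± 0.10), and the serine deaminase CHA1 (YCL064C, -2.07 ± 0.26).

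Of 34 general stress genes 19 rose and none fell at copper EC50, and of 27 heat shock genes 15 rose. Of 66 ribosome biogenesis genes 24 fell and none rose, among them the 60S assembly factor RPF2 (YKR081C, -1.48 ± 0.39), with a list mean of -0.82 ± 0.27. Sulfur genes rose in 19 of 27, with MET3 at 3.06 ± 0.24, and respiration genes in 6 of 46, with the cytochrome c oxidase subunit COX7 (YMR256C) at 1.43 ± 0.099. These 5 lists were called (camera adjusted p between 1.28e-14 and 6.22e-10, and adjusted p between 0.132 and 0.384 with an estimated correlation). Copper detoxification (3 of 4, the CUP1 pair among them), oxidative defence (6 of 27, OYE3 at 3.05 ± 0.10), aryl-alcohol dehydrogenases (1 of 6) and drug efflux (3 of 14) were higher as lists. Iron uptake (4 of 27 higher, FET3 at 2.19 ± 0.10, and 1 lower) and seripauperins (0 of 24) were also higher (for these 6, camera adjusted p between 4.45e-05 and 0.031, and adjusted p between 0.118 and 0.488 with an estimated correlation). Copper uptake (4 of 6), phosphate (4 of 17 lower and 1 higher), and amino acid synthesis (3 of 39) were lower. Cytosolic ribosomal proteins (1 of 137 lower and 2 higher), the proteasome (0 of 36) and histones (0 of 10) were lower too (for these 6, camera adjusted p between 0.000181 and 0.0171, and adjusted p between 0.0628 and 0.488 with an estimated correlation). In limma, copper changed 124 genes higher and 50 lower at EC10 (109 to 77 with median centring, 169 to 115 with processed signals, 156 to 105 in the series matrix) and 231 higher and 168 lower at EC50 (205 to 230 with median centring, 145 to 53 without background correction). The pair that held array 4 of the EC50 group, whose log2 ratios had an SD across genes of 0.628 against 0.526 to 0.558 on the other arrays, gave 339 calls when left out against 399.

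With mercury, TPO2, ERG3 and ERG25 rose and the transporters CTR1, ZRT1 and FET4 fell. At EC50 TPO2 rose by 3.61 ± 0.15, the sterol desaturase ERG3 (YLR056W) by 2.87 ± 0.074, the sterol oxidase ERG25 (YGR060W) by 2.65 ± 0.054, YRO2 by 2.86 ± 0.11 and the transcriptional repressor NRG2 (YBR066C) by 2.49 ± 0.27. COB (Q0105), the mitochondrially encoded cytochrome b, rose by 2.37 ± 0.56 at EC10 and 2.93 ± 0.17 at EC50, where 6 of 22 other mitochondrial probes were called higher as well. CTR1 fell (-1.99 ± 0.033 at EC10 and -2.96 ± 0.044 at EC50), as did ZRT1 (-2.13 ± 0.34 at EC50), the low-affinity iron transporter FET4 (YMR319C, -2.30 ± 0.19), ARO10 (-2.59 ± 0.33) and RGI1 (-2.43 ± 0.32). CUP1-1 fell in mercury at EC50 (-1.38 ± 0.0050), in contrast to its rise in silver, arsenite and copper.

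Of 23 ergosterol genes 6 rose and none fell at mercury EC50, with ERG4 (YGL012W) at 1.83 ± 0.018. Oxidative defence genes rose in 7 of 27 with 1 lower, among them the peroxidase GPX2 (YBR244W, 1.92 ± 0.17) and TRX2 (1.55 ± 0.13). Cell wall genes rose in 4 of 18, with GSC2 at 2.06 ± 0.13, and amino acid synthesis genes in 3 of 39, with ARG1 at 1.38 ± 0.12. These 4 lists were higher (camera adjusted p between 3.73e-09 and 0.0041, and adjusted p between 0.0572 and 0.42 with an estimated correlation). Also higher were sulfur genes (3 of 27), drug efflux (2 of 14, PDR5 (YOR153W) at 1.31 ± 0.051), aryl-alcohol dehydrogenases (1 of 6) and seripauperins, 0 of 24 (camera adjusted p between 0.000101 and 0.0391, and adjusted p between 0.169 and 0.541 with an estimated correlation). General stress genes were lower as a list, with 8 of 34 lower and 1 higher at EC50 and 15 of 34 lower at EC10, where GPH1 was at -2.64 ± 0.19 (adjusted p = 2.77e-07, and adjusted p = 0.377 with an estimated correlation). At EC50 general stress, copper uptake (3 of 6), histones (1 of 10), and the proteasome, respiration and mitochondrial ribosomal proteins, with no called member, were lower (camera adjusted p between 1.07e-07 and 0.00154, and adjusted p between 0.0628 and 0.575 with an estimated correlation). In limma, mercury changed 92 genes higher and 113 lower at EC10 (84 to 165 with median centring) and 112 higher and 61 lower at EC50. The totals ran from 95 without background correction to 348 with processed signals at EC10, and from 93 to 280 at EC50.

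With zinc, ARN2, FIT3 and FIT2 of iron uptake rose and the zinc transporters ZRT1 and ZRT2 fell. At EC50 ARN2 rose by 3.22 ± 0.027, the siderophore-binding cell wall proteins FIT3 (YOR383C) and FIT2 (YOR382W) by 2.88 ± 0.092 and 2.38 ± 0.14, FET3 by 2.36 ± 0.0086 and FTR1 by 1.76 ± 0.087. ZRT1 fell at both doses (-3.48 ± 0.23 and -3.18 ± 0.10), as did the low-affinity zinc transporter ZRT2 (YLR130C, -2.25 ± 0.031 and -2.54 ± 0.016). HXT6 (-2.69 ± 0.33), TMA10 (-2.55 ± 0.19), RGI1 (-2.51 ± 0.18) and HXK1 (-2.19 ± 0.14) also fell at EC50, while HSP30 rose by 2.92 ± 0.093 and TPO2 by 2.85 ± 0.043. Of 46 respiration genes 11 fell and none rose, among them cytochrome c, CYC1 (YJR048W, -1.67 ± 0.12), and aconitase, ACO1 (YLR304C, -1.44 ± 0.12).

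Of 27 iron uptake genes 14 rose at zinc EC50 and 11 at EC10, with none lower. Iron uptake, ribosome biogenesis (9 of 66, NOG2 at 1.81 ± 0.065), cytosolic ribosomal proteins (6 of 137, RPS8A at 2.03 ± 0.085), drug efflux (4 of 14, PDR5 at 1.67 ± 0.042), and seripauperins (0 of 24) were higher as lists at EC50 (camera adjusted p between 1.22e-10 and 0.0171, and adjusted p between 0.0572 and 0.502 with an estimated correlation). Respiration, general stress (10 of 34, with catalase CTT1 (YGR088W) at -1.49 ± 0.11), mitochondrial ribosomal proteins (1 of 43), histones (1 of 10) and the proteasome (0 of 36) were lower (camera adjusted p between 1.21e-09 and 0.000509, and adjusted p between 0.0734 and 0.54 with an estimated correlation). In limma, zinc changed 122 genes higher and 88 lower at EC10 (114 to 142 with median centring) and 141 higher and 103 lower at EC50 (135 to 177). The totals ran from 90 without background correction to 376 with processed signals at EC10, and from 110 to 437 at EC50.

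**Figure D2:**
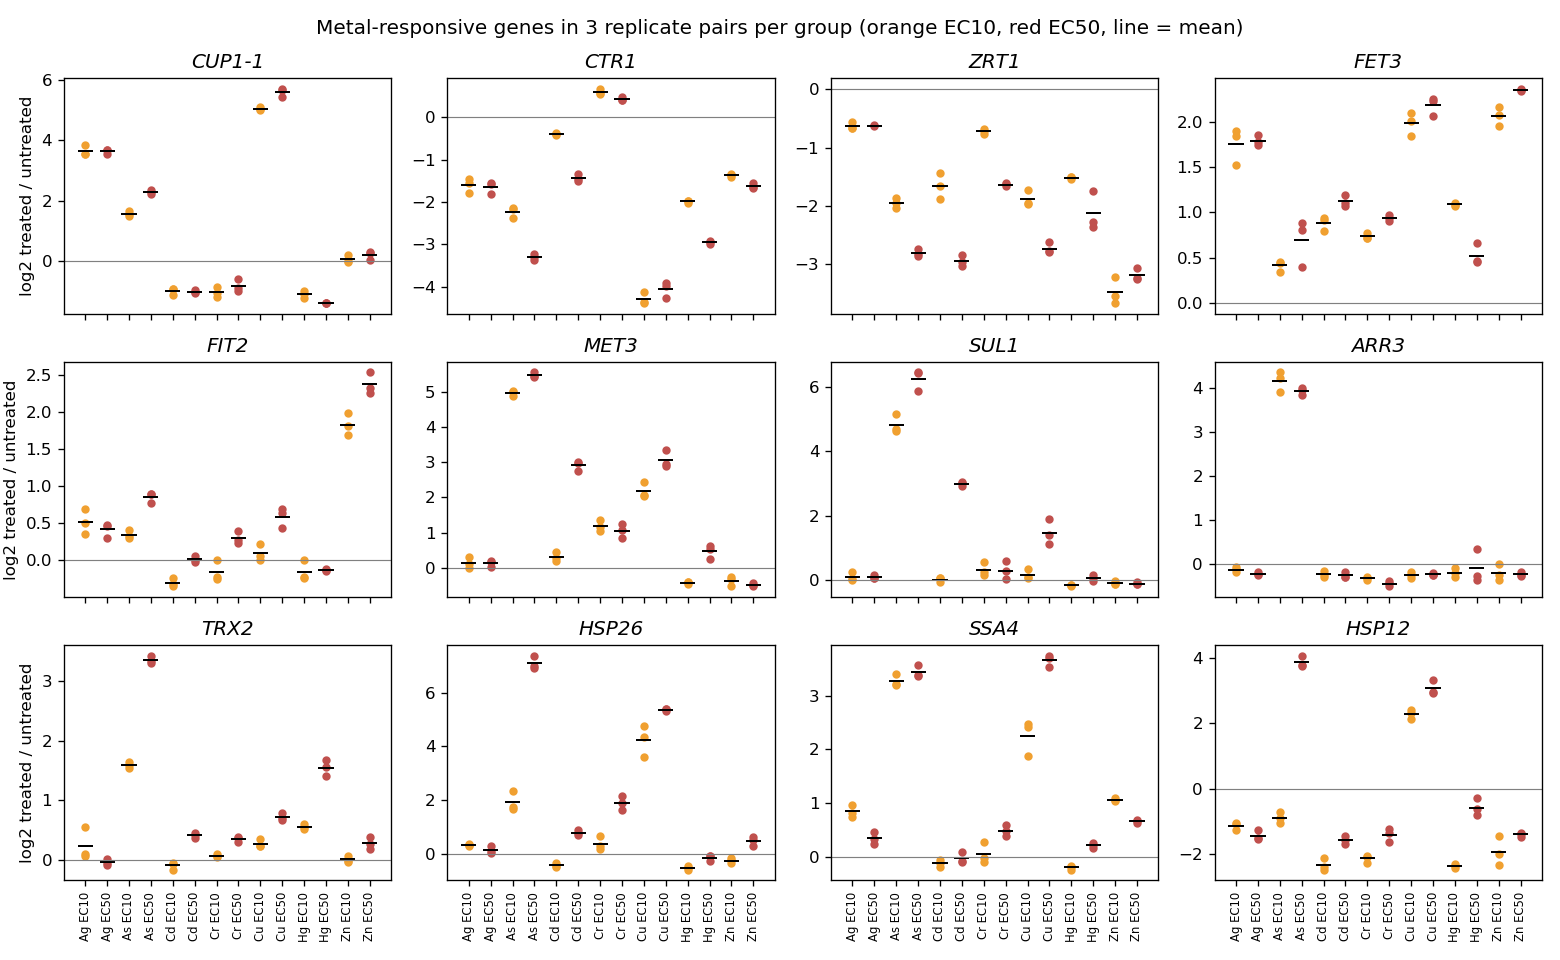
Log2 ratio of treated over untreated cells (vertical axes, each with its own range) for 12 metal-responsive genes in each metal at EC10 (orange) and EC50 (red). Each point is a dye-swap pair, 3 per group, and the line is their mean. CUP1-1 was at least at 5.60 in copper EC50 and -1.38 in mercury EC50, and ARR3 was called only in arsenite, at 4.17 and 3.93.

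Of 30 lists in 14 groups, 420 tests, camera called 174, 93 of them higher and 81 lower. In these the median, the mean and the test had 1 sign, and the counts of called members were the same when adjusted over the list alone in all 420. With an estimated correlation 1 call held, the DNA damage genes at arsenite EC50 (adjusted p = 0.0141). Sulfur and methionine genes were higher in 11 groups, histones lower in 13, the proteasome lower in 12 and higher in arsenite EC50 alone, and mitochondrial ribosomal proteins lower in 12, all but the copper groups. For these 4 lists adjusted p ran from 0.0572 to 0.718 with an estimated correlation. General stress genes were lower in 10 groups and higher in 3, copper at each dose and arsenite EC50, and ribosome biogenesis genes were higher in 9 and lower in those 3 (adjusted p = 0.197 to 0.734 with an estimated correlation). Growth of the cultures, which these lists can follow, was not analysed here. The copper uptake list was lower in 6 groups and higher in chromium at each dose (adjusted p = 0.0572 to 0.187 with an estimated correlation).

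Several fixed lists were called in no group. In arsenic transport, 2 of 4 genes rose at arsenite EC50 (camera adjusted p = 0.127). Of 17 glycolysis genes, 9 rose at copper EC50 and 6 at arsenite EC50 (adjusted p = 0.102 and 0.5). The hexose transporters had 4 of 17 lower and 1 higher in silver and in zinc at EC50 (adjusted p = 0.525 and 0.473). The hypoxic and heme list reached adjusted p = 0.236 at its lowest, the unfolded protein list 0.159, the haploid mating genes, which a diploid strain does not use, 0.298, and the meiosis genes 0.399. The phosphate permease PHO84 (YML123C), the vacuolar zinc transporter ZRC1 (YMR243C), the metallothionein CRS5 (YOR031W) and the cell wall protein FIT1 (YDR534C), named in advance, were called in none of the 14 groups.

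**Figure D3:**
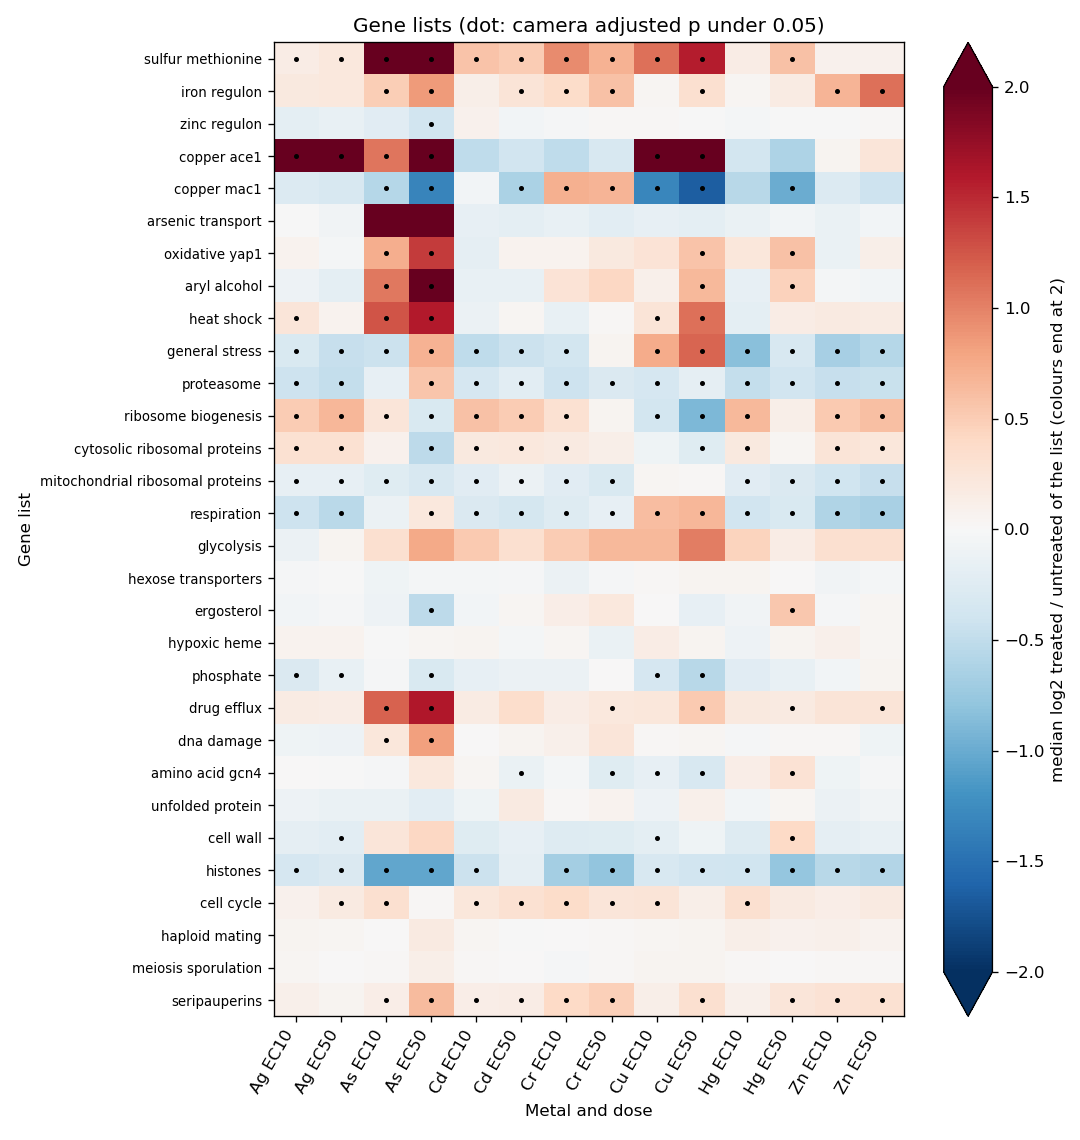
Median log2 ratio of the members of each of the 30 gene lists (rows) in each metal and dose (columns), with colours ending at 2 in either direction and a dot where camera's adjusted p was under 0.05. Sulfur and methionine genes reached 3.39 at arsenite EC50, and general stress genes were at 1.16 in copper EC50 and -0.56 in zinc EC50; the respiration value of 0.21 at arsenite EC50 was -0.11 with median centring.

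Between its doses arsenite changed most, with HSP26 (5.16, SE 0.17), the stress gene GRE1 (YPL223C, 4.77, SE 0.094) and HSP12 (4.77, SE 0.15) higher at EC50 than at EC10 and the acid phosphatases PHO3 (YBR092C, -2.28, SE 0.090) and PHO5 (YBR093C, -1.97, SE 0.094) lower. In cadmium SUL1 (2.98, SE 0.15), MET3 (2.60, SE 0.11) and MET14 (2.10, SE 0.10) were higher at EC50, and the cystathionine lyase STR3 (YGL184C, -1.40, SE 0.22), ZRT1 (-1.28, SE 0.11) and the sulfur regulator MET28 (YIR017C, -1.18, SE 0.13) lower. In mercury the carbonic anhydrase NCE103 (YNL036W, 2.29, SE 0.079), the oxidoreductase-like gene YNL134C (2.10, SE 0.076) and ERG3 (2.06, SE 0.063) were higher, and FET4 (-1.49, SE 0.064) and RAS1 (YOR101W, -1.10, SE 0.061), a small GTPase of nutrient signalling, lower. In copper OYE3 (2.78, SE 0.056), BTN2 (YGR142W), a sorting chaperone for misfolded proteins (2.08, SE 0.24), and ROQ1 (YJL144W), a gene of protein quality control (1.70, SE 0.14), were higher. CHA1 (-1.18, SE 0.091), the amino acid permease DIP5 (YPL265W, -1.11, SE 0.083) and the heme synthesis gene HEM13 (YDR044W, -1.04, SE 0.099) were lower. In chromium RGI1 (1.66, SE 0.18), HSP30 (1.55, SE 0.37) and HSP26 (1.52, SE 0.17) were higher, with ARN2 (1.21), which was chosen after its values were seen, and the riboflavin transporter MCH5 (YOR306C, -1.17, SE 0.12) and the folate enzyme MTD1 (YKR080W, -1.04, SE 0.14) lower. The remaining lower genes of cadmium, the methionine permease MUP3 (YHL036W, -1.11) and CTR1 (-1.03), were also chosen after their values were seen.

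In limma, EC50 differed from EC10 in 255 higher and 49 lower genes for arsenite, 56 and 2 for mercury, 30 and 3 for copper, 8 and 5 for cadmium and 4 and 2 for chromium. For silver and zinc limma called 0 genes, with 1210 and 1206 genes at an unadjusted p under 0.05, and 245 and 476 genes at an adjusted p under 0.05 with no minimum fold. Between the doses of silver the processed signals and the series matrix each gave 3 calls, and between those of zinc 5 and 2, with 1 call for zinc under array weights and when 1 pair was left out. Without background correction the calls of ZRT1 (-0.89), STR3 (-0.88), MET28 (-0.98), FET4 (-0.98), RAS1 (-0.89), CHA1 (-0.997), DIP5 (-0.62), HEM13 (-0.91), HSP26 in chromium (0.95), MCH5 (-0.96) and MTD1 (-0.92) were lost, and those of MTD1 (-0.99, -0.92 and -0.91) and HEM13 (-0.95) also when 1 pair was left out. Of all 6 calls between the doses of chromium, only 2 were kept without background correction.

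Against the mean of the other 6 metals at EC50, silver stood higher in CUP1-1 (2.83, SE 0.071) and ZRT1 (1.94, SE 0.099) and lower in HSP26 (-2.43, SE 0.13). Arsenite stood higher in OYE3 (6.98, SE 0.043), OSI1 (6.44, SE 0.066) and FLR1 (6.28, SE 0.050) and lower in OLE1 (-2.69, SE 0.052). Cadmium stood higher in 3 genes, SUL1 (1.65, SE 0.11, lost without background correction at 0.61), MET3 (1.29, SE 0.085) and MET5 (1.12, SE 0.084), and lower in CUP1-1 (-2.60, SE 0.071). Chromium stood higher in CTR1 (2.94, SE 0.060), FRE7 (2.89, SE 0.063), FRE1 (2.50, SE 0.052) and FET4 (2.15, SE 0.049), and copper in CUP1-1 (at least 5.12, its treated channel being saturated), HSP26 (3.65, SE 0.13) and HSP12 (3.51, SE 0.11). Mercury stood higher in ERG3 (2.41, SE 0.048), ARG1 (2.10, SE 0.070), ERG25 (2.05, SE 0.035) and the alcohol acetyltransferase ATF2 (YGR177C, 1.92, SE 0.036). Zinc stood higher in ARN2 (2.26, SE 0.075), FIT2 (2.04, SE 0.065), FIT3 (1.87, SE 0.065) and the siderophore transporter ENB1 (YOL158C, 1.48, SE 0.059), and lower in PTR2 (-3.08, SE 0.081) and MET3 (-2.65, SE 0.085). The CUP1-1 values of silver and cadmium here count that saturated copper value among the other metals, so they are upper limits.

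In limma these contrasts called 18 higher and 66 lower genes for silver, 433 and 85 for arsenite, 3 and 40 for cadmium, 17 and 22 for chromium, 146 and 180 for copper, 34 and 34 for mercury and 18 and 72 for zinc. At EC10 the counts were 7 and 13 for silver, 159 and 4 for arsenite, 1 and 15 for cadmium, 18 and 13 for chromium, 134 and 65 for copper, 5 and 50 for mercury and 7 and 24 for zinc. The groups of 5 or fewer at EC10 were chosen after their values were seen. They were CTR1 higher in cadmium (1.42), FET4 (-1.34), OLE1 (-1.14), the glycogen synthase GSY1 (YFR015C, -1.01) and FET3 (-1.01) lower in arsenite, and ARG1 (1.24), the glucose repressor MIG2 (YGL209W, 1.08), GPX2 (1.06), TPO2 (1.06) and COB (1.04) higher in mercury. The mean of the other metals includes arsenite and copper, so a gene that rose most with those, such as HSP26, stands lower in silver and in mercury (-2.77, SE 0.13). Likewise CTR1, which fell with silver, arsenite, copper and mercury, stands higher in chromium at EC50, where it was not called against untreated cells. ZRT1 fell with arsenite, cadmium, copper, mercury and zinc, so its higher standing in silver need not be a rise. MET3 stands higher in cadmium although it rose further with arsenite and copper.

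At EC50 8 genes were higher in all 7 metals and 2 lower (together 27 with processed signals and 25 in the series matrix), where independent lists of these sizes would share 2.51e-08 and 5.79e-10. YRO2 ranged from 1.67 in silver to 4.33 in arsenite, HSP30 from 1.57 in copper to 4.64 in arsenite, and GOT1 (YMR292W), a protein of vesicle transport to the Golgi, from 1.39 in cadmium to 2.02 in arsenite. MAK31 (YCR020C-A), a subunit of a protein acetyltransferase, ranged from 1.14 in silver to 1.53 in zinc, and PCL1 from 1.14 in arsenite to 2.90 in copper, with its call in silver lost without background correction (0.70). YGL088W, YMR193C-A and YML090W completed the set, and the last pair of identifiers are absent from the reference gene table used for names. RGI1 was lower throughout, from -2.51 in zinc to -1.46 in arsenite, and ARO10 from -2.59 in mercury to -1.10 in zinc. At EC10 9 genes were higher in all 7 metals and 4 lower (together 32 with processed signals, 26 in the series matrix and 5 without background correction), among them RPS8A from 1.62 in copper to 2.19 in mercury and TPO2 from 1.25 in copper to 3.29 in mercury. The 4 lower genes were RGI1, TMA10, the cell shape gene AFR1 (YDR085C) and the maltase MAL12 (YGR292W), the last pair chosen after their values were seen. The metals share untreated cells as their reference, so part of the excess over independent lists may come from the control RNA. At least 5 metals shared 39 higher and 19 lower genes at EC50, and 39 and 31 at EC10.

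The profiles of the metals were set against each other across 6230 genes, which are not independent replicates. At EC50 the 21 pairs of metals had a median Pearson r of 0.624 and a median Spearman rho of 0.618. Silver and zinc were closest (r = 0.877) and silver and arsenite furthest apart (r = 0.208), while arsenite and copper were at r = 0.624. At EC10 the median r was 0.635 and the median rho 0.772, and cadmium and mercury were closest (r = 0.949). The doses of 1 metal correlated at r = 0.776 in arsenite to 0.970 in silver. The median covariance between metals was 0.122 at EC50 and 0.135 at EC10. In 20 simulations of unchanged groups that share a control, the covariance was 0.0025 if the control gave all the spread between pairs, and 0.00127, with r = 0.5, if it gave 1 part in 2. A control pool common to all arrays adds no spread between pairs, so these simulations do not limit its share. Untreated RNA common to both doses cancels in the change from EC10 to EC50. Between metals those changes correlated at a median r of 0.27 (-0.452 to 0.564 over the 21 pairs). They measure the change between doses and not the whole response, so they do not give the share of the control either.

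**Figure D4:**
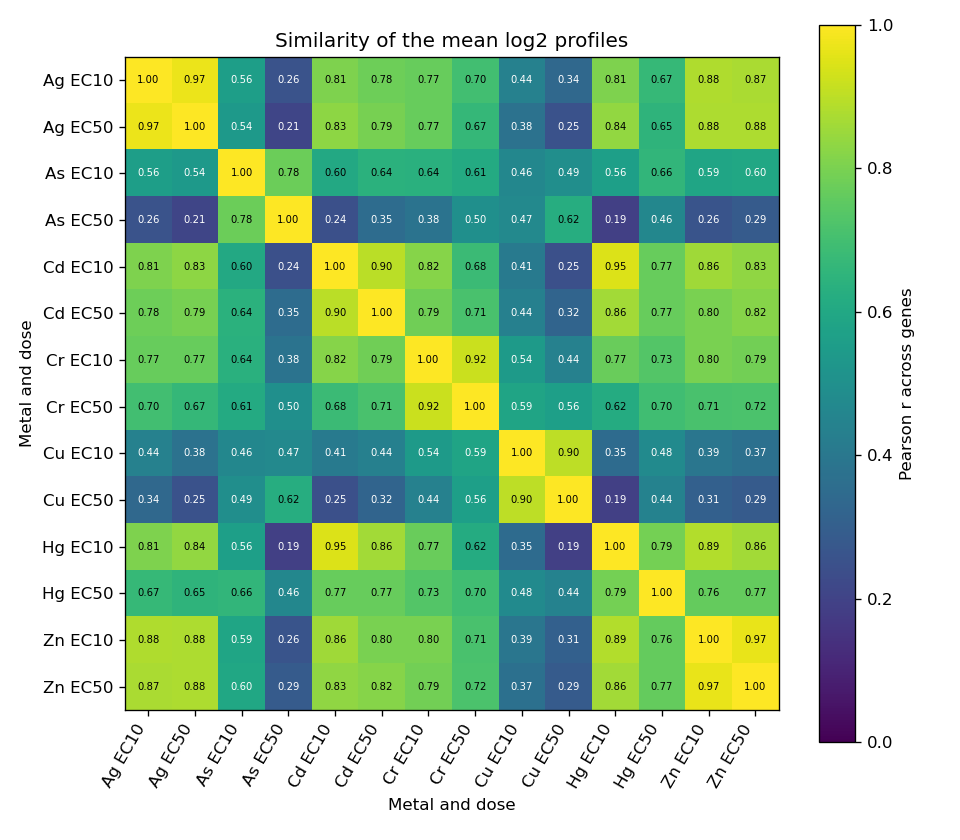
Pearson correlation across 6230 genes of the mean log2 ratios of each metal and dose with every other, coloured from low to high. Silver and zinc at EC50 were at r = 0.877 and silver and arsenite at EC50 at r = 0.208.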

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

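The test of a dose effect in the copper and arsenite pattern and the adjustment over all pairs of metals were chosen only after the result was seen. The metal pairs below were set against each other because their lists or genes were called in opposite directions at EC50, and p is adjusted over 30 lists (or 6230 genes) and all 21 pairs of metals.

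Several lists and HSP12 were opposed between metals. General stress genes stood 1.78 higher in copper than in zinc (median difference in log2 over 34 genes, all higher in copper; camera adjusted p = 3.24e-18, and adjusted p = 0.0467 with an estimated correlation). Ribosome biogenesis genes stood 1.54 higher in silver than in copper (66 of 66; camera adjusted p = 1.2e-29, and adjusted p = 0.0912 with an estimated correlation, where the call is lost), cytosolic ribosomal proteins 0.835 higher in silver than in arsenite (131 of 137; camera adjusted p = 2.12e-20, and adjusted p = 0.0269 with an estimated correlation), respiration genes 1.30 higher in copper than in zinc (46 of 46; camera adjusted p = 1.63e-23, and adjusted p = 0.0224 with an estimated correlation) and proteasome genes 0.932 higher in arsenite than in silver (36 of 36; camera adjusted p = 8.57e-13, and adjusted p = 0.00479 with an estimated correlation). The stress gene HSP12 stood 5.46 higher in arsenite than in cadmium, with 3 of 3 pairs of each metal on its side of 0 (limma adjusted p = 4.98e-27).

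Higher general stress and lower ribosome biogenesis genes as lists at EC50 of copper (19 of 34 and 24 of 66 called) and arsenite (13 of 34, with 3 lower, and 1 of 66) were weighed as a pattern, though none of the 4 list calls held with an estimated correlation (adjusted p = 0.217 to 0.734). The choice among 5 scalings was excluded as the whole of it, as the smallest median in its direction over them was 0.243 (ribosome biogenesis in arsenite without background correction). All 5 set the middle of an array's ratios near 0, so they cannot show a shift of all transcripts together. In arsenite the sizes depend on the scaling: with median centring the stress median went from 0.69 to 0.31 and that of ribosome biogenesis from -0.30 to -0.59. A few deviating arrays were also excluded, since 12 of 12 arrays had both signs. A response that grows with dose stays open, since the median change from EC10 to EC50 was 1.01 and -0.691 in arsenite but 0.143 and -0.485 in copper, where both lists were called at EC10 already. At arsenite EC10 both lists were called in the opposite direction (medians of -0.43 and 0.25), calls that were also lost with an estimated correlation. The ribosome biogenesis median there was 0.106 with median centring. The change in the arsenite medians was thus a turn of sign and not the growth of a pattern present at EC10. A general stress program with slowed growth may explain it, as a hypothesis that growth measured in these cultures, or doses matched for growth, would test, and a difference in the growth effect of the doses cannot be told apart from it here.

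Other lists and CUP1-1 were also opposed. Copper uptake genes stood 2.63 higher in chromium than in copper (6 of 6 members; camera adjusted p = 5.51e-08, and adjusted p = 0.000697 with an estimated correlation). CUP1-1 stood at least 6.98 higher in copper than in mercury, again in 3 of 3 pairs of each (limma adjusted p = 2.62e-36), with its treated channel saturated in copper. Ergosterol genes stood 1.40 higher in mercury than in arsenite (22 of 23; camera adjusted p = 5.27e-14, and adjusted p = 0.000814 with an estimated correlation), amino acid synthesis genes 0.537 higher in mercury than in copper (38 of 39; camera adjusted p = 1.06e-13, and adjusted p = 0.0135 with an estimated correlation), and cell wall genes 0.661 higher in mercury than in silver (17 of 18; camera adjusted p = 2.05e-10, and adjusted p = 0.0214 with an estimated correlation).

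Array 4 of copper at EC50 stood apart from the other 5 in the SD of its log2 ratios across genes, 0.628 against 0.526 to 0.558. This was 1 of 14 groups, and chance would mark about 1 group in 20. Without the pair that holds it, copper at EC50 gave 339 calls against 399, and against the other metals 270 against 326.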

How the results depend on the processing

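The alternatives with the slide or the chosen pair as a random block were chosen only after the data were seen. No named gene reversed under an alternative run for it, but the median of the respiration list at arsenite EC50, a called list, went from 0.21 to -0.11 with median centring. Counts were compared by their totals, which do not show the split into higher and lower genes. In silver and copper at EC50, cadmium at EC10, and chromium and zinc at each dose, higher calls outnumbered lower ones as reported. With median centring lower calls outnumbered higher ones there. Lower calls at arsenite EC50 went from 177 to 399. All 37 counts of called genes stayed within 1.5 times the reported count with median centring, with no filter or a stricter filter on dim probes, with consecutive pairs, with arrays as separate samples, with either random block and with groups fitted alone, as did the 7 counts between doses with a replicate number block. With array weights 36 of 37 did, the exception being the doses of zinc (1 call against 0). Consecutive pairs, separate arrays, random blocks and groups fitted alone leave the group means almost unchanged. Against untreated cells 4600 to 5249 of 6230 genes had a limma adjusted p under 0.05, so the 2-fold limit set those counts. Their stability under these settings therefore says little. Arsenite at EC50 kept its pairs in the consecutive setting, since its consecutive arrays do not all have opposite dyes. The brightest-probe alternative was not run, since each open reading frame had 1 probe, nor the scan date blocks, since the files give only an extraction time, all on 1 day. Of the counts below, which moved beyond that, the cause was not tested except where stated.

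Without background correction, the counts against untreated cells (EC10 then EC50) were 41 and 62 for silver, 182 and 432 for arsenite, 49 and 69 for cadmium, 83 and 87 for chromium, 102 and 198 for copper, 95 and 93 for mercury and 90 and 110 for zinc. Between doses they were 186 for arsenite, 6 for cadmium, 2 for chromium, 15 for copper and 32 for mercury. At EC50, a metal against the others gave 47 for silver, 27 for cadmium, 154 for copper, 40 for mercury and 52 for zinc. At EC10, a metal against the others gave 10 for silver, 7 for cadmium, 17 for chromium, 98 for copper, 21 for mercury and 16 for zinc. The genes changed in all 7 metals were 5 at EC10.

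With processed signals, the counts against untreated cells (EC10 then EC50) were 234 and 340 for silver, 463 for arsenite (EC10 alone), 200 and 207 for cadmium, 307 and 273 for chromium, 284 for copper (EC10 alone), 348 and 280 for mercury and 376 and 437 for zinc. Between doses they were 3 for silver, 11 for chromium, 59 for copper and 5 for zinc. At EC50, a metal against the others gave 154 for silver, 62 for chromium and 143 for zinc. At EC10, a metal against the others gave 28 for cadmium. The genes changed in all 7 metals were 32 at EC10 and 27 at EC50.

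In the series matrix values, the counts against untreated cells (EC10 then EC50) were 226 and 310 for silver, 183 and 192 for cadmium, 286 and 242 for chromium, 321 for mercury (EC10 alone) and 346 and 398 for zinc. Between doses they were 3 for silver, 11 for chromium and 2 for zinc. At EC50, a metal against the others gave 140 for silver. At EC10, a metal against the others gave 25 for cadmium. The genes changed in all 7 metals were 26 at EC10 and 25 at EC50.

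With no minimum fold, the counts against untreated cells (EC10 then EC50) were 4600 and 4875 for silver, 4820 and 5249 for arsenite, 4787 and 4687 for cadmium, 4831 and 4746 for chromium, 4656 and 5003 for copper, 5011 and 4732 for mercury and 5035 and 5043 for zinc. Between doses they were 245 for silver, 4249 for arsenite, 1405 for cadmium, 1254 for chromium, 2330 for copper, 2853 for mercury and 476 for zinc. At EC50, a metal against the others gave 3942 for silver, 4944 for arsenite, 3804 for cadmium, 3226 for chromium, 4177 for copper, 2979 for mercury and 4088 for zinc. At EC10, a metal against the others gave 2999 for silver, 3048 for arsenite, 2369 for cadmium, 2856 for chromium, 3948 for copper, 2993 for mercury and 3182 for zinc. The genes changed in all 7 metals were 1927 at EC10 and 1457 at EC50. These counts rise by construction, since a condition was dropped.

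Leaving out 1 pair at a time moved 1 result, the doses of zinc, at 0 to 1 (1 without replicate 2 of EC10). Ranges for the other doses were 304 to 320 in arsenite, 12 to 16 in cadmium, 5 to 9 in chromium, 27 to 40 in copper and 50 to 62 in mercury. Against untreated cells the widest range was in copper at EC50, 339 to 428. Genes changed in all 7 metals ran from 10 to 17 at EC10 and stayed at 10 at EC50, and called list tests from 171 to 176.

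Of 420 list tests, camera called 174, camera with an estimated correlation 1 and fry 370. Fry tests a list by itself and camera against the other genes, so their calls answer different questions. With processed signals 4 list calls were lost and 6 gained, and leaving out a pair lost 15 and gained 13 over all such runs. The median correlation of profiles at EC10, reported as 0.635, was 0.655 with processed signals, 0.664 in the series matrix and 0.586 over called genes alone, and that at EC50 moved by less than its spread.

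Of 823 values of named genes, 111 lost their call without background correction, 38 with median centring (3 gained), 7 with array weights and 1 with processed signals (12 gained), and of the 793 in the series matrix 4 lost it and 4 gained it. None lost it with no filter on dim probes, separate arrays, either random block or groups fitted alone, and of the 793 left by the stricter filter and the 822 in consecutive pairs none did. Leaving out pairs lost 31 calls and gained 4, against 3490 values on the same side. Signal over background limits the ratios of dim genes: adding an offset or leaving the background in draws them toward 0.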

Other observations

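The tests of a dye effect on the shared genes, the tests on rising and falling genes apart, on genes chosen at EC50 and without a metal, and the count of relabellings by the arsenite and copper pairs they held were chosen only after the result was seen.

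In arsenite the nitroreductase-like gene FRM2 (YCL026C-A) rose by 6.12 ± 0.024 at EC10 and 6.32 ± 0.20 at EC50, GRE2 (YOL151W), a methylglyoxal reductase, by 4.72 ± 0.0069 and 5.64 ± 0.22, HSP31 (YDR533C), a glyoxalase and chaperone, by 3.31 ± 0.034 and 4.17 ± 0.071, and the exporter ATR1 (YML116W) by 3.64 ± 0.20 and 3.66 ± 0.11. The iron-sulfur scaffold gene ISU2 (YOR226C) rose by 1.71 ± 0.22 and the copper-transporting ATPase CCC2 (YDR270W) by 2.00 ± 0.16, while IZH1 (YDR492W), a membrane protein gene that responds to zinc, fell (-1.82 ± 0.13). The gene HSP31 also rose in copper at EC50 (2.50 ± 0.17), and ATR1 (1.87 ± 0.14) and GRE2 (2.09 ± 0.15) in mercury.

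In mercury at EC50 phosphoglucomutase PGM2 (YMR105C) fell (-1.63 ± 0.19), as did glycogen synthase GSY1 (YFR015C, -1.47 ± 0.16), and the glucose-signalling gene EMI2 (YDR516C) fell in silver (-2.03 ± 0.040) and cadmium (-1.77 ± 0.041). In copper at EC50 the cell wall stress gene SPI1 (YER150W) rose by 3.00 ± 0.13 and the second sulfate permease SUL2 (YLR092W) by 3.22 ± 0.21. The G1 cyclin CLN1 (YMR199W) rose by 1.51 ± 0.25 in copper at EC10 and the mitotic cyclin CLB1 (YGR108W) by 1.36 ± 0.28, and in chromium at EC10 by 1.43 ± 0.017 and 1.23 ± 0.093.

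Genes changed in 1 direction in all 7 metals formed a pattern. A constant dye effect that does not turn with the dyes cancels in pair means, so by design it cannot be the cause. The lowest of the 14 medians of genes chosen at EC10 in the other 6 metals was 0.577 (SD 0.298 between pairs, in copper at EC50). These genes were both chosen and read in pair means, so that median is no further test of a dye effect. For control RNA that differed from treated RNA in 1 way on every array, the highest median was 3.55 times the lowest (1.52 without copper, 1.86 for genes chosen at EC50). The ratio was 1.90 for rising genes and 6.82 for falling genes (3.89 without copper, 2.12 for genes chosen at EC50, 1.67 of these without silver). These ratios set different genes against each other, such as 4 falling genes in mercury and 15 in copper, so they cannot decide it. In the same 5 falling genes of arsenite the median went from -1.34 (SD 0.108 between pairs) at EC10 to -0.597 (SD 0.0578) at EC50. In the 4 falling genes of mercury the median went from -2.32 (SD 0.165) to -1.28 (SD 0.11), and in the 4 of chromium from -1.98 (SD 0.0969) to -1.43 (SD 0.191). Beyond that SD, falling genes chosen at EC10 fell less at EC50 in these 3 metals and more in 2. The values of arsenite, mercury and chromium argue against such control RNA as the whole cause for these genes. Falling genes chosen at EC50, however, fell by 1.34 and 1.46 in arsenite, 1.63 and 1.65 in mercury and 1.17 and 1.19 in chromium. Such control RNA stays open for the other genes, the rising ones included. A shared response that grows with dose stays open, since genes chosen at EC10, a choice that favours those changed there, had a larger median at EC50 in 3 of 7 metals (5 for rising genes, 3 for falling), and those chosen at EC50 in 5 (4 and 5). Beyond the SD between pairs, the median of genes chosen at EC10 was larger at EC50 in 1 metal and smaller in 3. For genes chosen at EC50 it was larger in 1 and smaller in 1. A response to metal or handling common to the treated cultures may remain, as a hypothesis that cultures handled alike without metal would test.

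COB rose in mercury, by 2.37 at EC10 and 2.93 at EC50, and also in other metals, so that transcripts of the mitochondrial genome rising as a class may account for it. The median of the other 22 mitochondrial probes at mercury EC50 was 0.553, with 6 called higher and none lower, which neither excludes nor bears out a rise of the class. Over the 14 groups that median ran from 0.073 in copper at EC10 to 0.553. No biological explanation was tested.

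Other splits of the samples were counted for the comparisons between groups. Between doses, 10 splits of the 6 pairs of a metal are too few for a share under 0.05. The real split gave 304 calls in arsenite, 13 in cadmium, 6 in chromium, 33 in copper and 58 in mercury, each as many in 1 of 10 splits, with the highest other split at 3 in copper and 0 in the rest. In silver and zinc 10 of 10 splits gave 0 calls. For a metal against the other 6 at EC50, 100 labellings of the 21 pairs were counted, the real one and 99 drawn at random. Chance was excluded for arsenite (518 calls, highest other 218, as many in 1) and copper (326, 298, 1). In the same draws, however, the groups labelled silver and chromium reached 358 and 363 calls, above the 326 of copper. In mercury (68, 213, 2) and zinc (90, 224, 3) few draws gave as many. However, only 4 and 5 of their draws put at least 2 pairs of arsenite or 2 of copper into the drawn group. In silver, cadmium and chromium 9, 11 and 14 draws did, so the low shares of mercury and zinc may come from the draw and do not exclude chance. For silver (84, 358, 9), cadmium (43, 298, 10) and chromium (39, 363, 13) the relabellings did not exclude chance either, but they mix metals whose responses differ. The 8, 9 and 12 other draws with as many calls each put at least 2 pairs of arsenite or 2 of copper into the drawn group, and draws with neither metal in it gave at most 31, 39 and 12 calls. Counts several times the real one, as in mercury and zinc too, thus point to that structure of the samples.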
